A study of Mus musculus with 8 samples.

How the data were processed

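Gene expression was measured in inguinal white adipose tissue, the subcutaneous fat depot of the groin, from male C57BL/6 littermates aged 12 weeks on standard chow. There were 4 mice lacking the lysophosphatidic acid receptor Lpar4 (KO) and 4 wild-type mice (WT), each a biological replicate with its own array. Per the labels, 100 ng of total RNA per sample was amplified, labelled with biotin and hybridised to a 3' expression array. The authors deposited a table of log2 values, with 45101 probe sets in each of the 8 arrays. R 2.14.0 is named in the submitters' processing notes. The background correction, normalisation and summarisation methods are not given in the sources used here. The log2 scale itself was read from the deposited values, which ran from 4.93 to 14.3, with array medians of 6.73 to 6.74.

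Most deposited values hardly moved between arrays. The SD over the 8 arrays was under 0.01 for 78.7% of the probe sets, called near constant here, and the remaining 9606 probe sets are called varying. How this arose is not known here. The variances of genes then had little in common, and limma estimated only 0.332 prior degrees of freedom over all genes, against 2.00 over varying genes, so the test over all genes leaned almost wholly on each gene's own spread. Genes were named through the platform annotation given with the table. It paired 34945 probe sets with a single gene, 932 with several genes and listed 9160 without a single gene name; 64 were control probe sets. Of the single-gene probe sets, 34741 had a gene identifier in the GRCm38.p6 gene table, and 0 symbols needed an update. No genome build is named for the array values, so positions are not printed.

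Each gene was represented by its brightest probe set over all 8 arrays, which gave 18193 genes, of which 5173 varied. KO was compared with WT with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera from limma, with a preset inter-gene correlation of 0.01 and adjustment over the 44 lists with at least 5 measured members; fry and camera with an estimated correlation were run beside it. Of 956 listed genes, 873 were measured, 17 of them matched by a synonym. Single values were compared with two-sided exact permutation tests, whose smallest possible p for 4 against 4 arrays is 0.0286. The number of arrays limits the precision of every value.

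The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Lpar4, the 10 largest increases and 10 largest decreases among passing genes whose groups do not overlap, up to 4 members with the smallest p of each list described, and a set of adipose markers. Genes outside it are stated to be chosen after their values were seen. The SD limit of 0.01, the test of varying genes only, and a block of replicate numbers 1 and 2 against 3 and 4 were chosen after seeing the data.

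The labels number the replicates 1 to 4 in both genotypes without saying what a number shares. Deviations from the genotype means of same-numbered KO and WT arrays correlated across genes at 0.315, 0.486, 0.189 and 0.244, all over the 0.1 needed to treat the numbers as pairs; this pairing comes from the data alone. KO 3 correlated better with WT 4 (0.364) and KO 4 with WT 3 (0.266) than with their own numbers, so the arrays parted rather into numbers 1 and 2 against 3 and 4. Over all genes 0 genes passed with the number as a replicate block, so the block ended every single-gene call made there. Gene counts and calls are of the fit without the block, fixed before the data were examined, unless stated. That fit ignores the pairs that met the rule, so its single-gene calls over all genes hold only if the arrays are unpaired. For single genes the blocked value given, where it changes a call, is that among varying genes, a set chosen after seeing the data.

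The gene test was tested on simulated data for KO against WT, 4 against 4, with normal noise at each gene's own SD and 50 varying genes changed at each size. With all 18193 genes it recovered 30% of changes of 0.3 log2, 56% at 0.6, 80% at 1 and 92% at 1.5, with 7 false calls. With the 5173 varying genes it recovered 48%, 72%, 90% and 96%, with 11 false calls. The simulated genes were independent, which real genes are not. Other alternatives covered dim genes, the probe set per gene, normalisation, the variance model, a per-gene Welch test and leaving out each array.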

Results

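The transcriptome of inguinal white adipose tissue was compared between 4 male Lpar4-KO mice and 4 male WT littermates aged 12 weeks. The comparison addresses which genes differ in this fat depot when Lpar4, an X-linked G protein-coupled receptor for lysophosphatidic acid, is missing. Values are log2 signals, and differences are KO minus WT. The 8 arrays had near-equal medians, from 6.73 to 6.74, and detection calls were not used here.

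Lpar4 was represented by 3 probe sets that did not move the same way. Probe set 1452424_at fell from 6.93 ± 0.10 in WT to 5.81 ± 0.07 in KO (SD, n = 4 each), a difference of -1.12 with a limma adjusted p of 0.0104 over all probe sets. Its mean stood at percentile 57.0 of all probe sets in WT and at percentile 3.37 in KO, among the dimmest values of the arrays, so the size of this difference is not exact. Probe sets 1434186_at (0.71) and 1439665_at (0.53) were higher in all 4 KO arrays than in any WT array, but did not pass the same limma test (adjusted p = 0.144 and 0.128). The exact permutation p was 0.0286 for each of the 3 probe sets, the smallest this design can give. Where each probe set lies relative to the deleted part of Lpar4 is not known here, so which of them can check the genotype labels is not known either. The brightest probe set, 1439665_at, stands for Lpar4 in the gene-level test (adjusted p = 0.111 over all genes). Among varying genes only, a test chosen after seeing the data, its adjusted p was 0.0300.

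**Figure D1:**
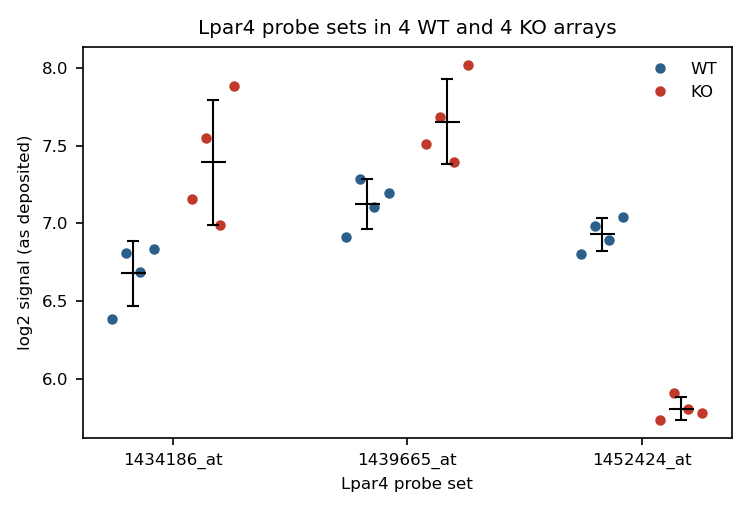
Log2 signal of the 3 Lpar4 probe sets in each WT (blue) and KO (red) array, with the mean and SD of 4 arrays in black. Probe set 1452424_at lies at 5.81 in KO and 6.93 in WT, while the others are higher in KO.

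The largest increases in KO were those of Nabp1, a single-stranded DNA binding protein (1.41 ± 0.17, SE, n = 4 against 4), the carboxylesterase Ces1f (1.35 ± 0.14), the cytochrome P450 Cyp2f2 (1.34 ± 0.24) and the adipocyte galectin Lgals12 (1.23 ± 0.24). They were followed by the opsin Opn3 (1.05), the glutathione transferase Gsta4 (1.02), the predicted gene Gm10419 (0.98), pyruvate carboxylase Pcx (0.87), the glycerol-3-phosphate acyltransferase Gpat3 (0.77) and Pnldc1 (0.72). The largest decreases were those of the secreted protein Ccn5 (-1.85 ± 0.17), the small heat shock protein Hspb7 (-1.50 ± 0.21), Tmem45b (-1.43 ± 0.25), the imprinted gene Peg3 (-1.33 ± 0.20) and smooth muscle actin Acta2 (-1.26 ± 0.11). Zim1, an imprinted neighbour of Peg3 (-1.17), the actin-binding protein Synpo2 (-1.17), the matrix protein Thbs2 (-1.16), S-adenosylhomocysteine hydrolase Ahcy (-1.13) and Vat1l (-1.09) completed the 10. The probes of Ces1f and Acta2 are shared with other transcripts, so related genes can contribute to their values. By their probe set suffixes, the same limit holds for Ndufa12, Ndufab1, Dlat, Cnp, Rpl35, Srxn1, Phgdh and Plagl1, named further on. Zim1 and Vat1l in KO (percentiles 3.60 and 19.6 of all probe sets) and Gm10419 in WT (percentile 13.7) were dim. Signal over background was not analysed here, so the sizes and ranks of these 3 differences are not exact.

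In all, 733 of 18193 genes passed without the replicate block, 434 higher and 299 lower in KO. Of these, 590 varied between arrays (344 higher, 246 lower), with a median absolute difference of 0.32. The other 143 were near constant, and the largest difference among them was 0.01. At 1.5-fold or more there were 23 higher and 57 lower genes, and at 2-fold or more 6 and 15. The 2 genotypes did not overlap in 1720 of the 5173 varying genes (33.2%), against 2.86% if all 70 assignments of the arrays were equally likely. That figure ignores the pairs that met the rule. Genes also move together, and varying genes were kept by a spread that includes the genotype difference, so this share is not a test.

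The control probe sets for 18S ribosomal RNA were also higher in all 4 KO arrays than in any WT array (0.44, 0.22 and 0.28). The count of passing genes depended on the fit. With the replicate number as a block, 0 genes passed in limma, although 3703 had an unadjusted p under 0.05 against 4172 without the block. Leaving out KO arrays 1 to 4 in turn left 131, 253, 10 and 230 genes, and leaving out WT arrays 1 to 4 left 212, 132, 193 and 220. Among varying genes only, a choice made after seeing the data, 1402 genes passed, or 1011 with the replicate block (533 higher, 478 lower). All 20 genes named above passed in both of these fits, which reuse the arrays that selected them and so give no independent support. They were picked for groups that do not overlap, so each had to have the same sign in numbers 1 and 2 as in 3 and 4.

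**Figure D2:**
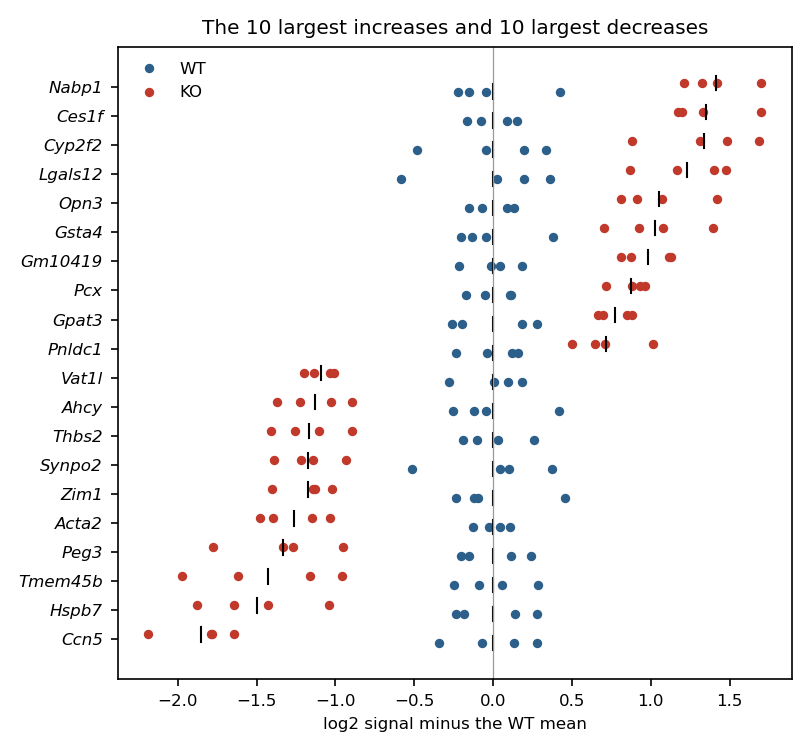
Log2 signal minus the WT mean for the 10 largest increases and 10 largest decreases, with a point per array (WT blue, KO red) and black lines at the means of 4 arrays. The genotypes do not overlap, from Ccn5 (-1.85) to Nabp1 (1.41).

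Passing genes of mitochondrial energy metabolism were higher in KO, with 1 exception in the mitochondrial ribosome. Of 34 measured complex I genes 9 rose and 0 fell, among them Ndufb3 (0.42), Ndufab1 (0.27), Ndufa12 (0.25) and Ndufb6 (0.24); adjusted over the list alone 22 rose and 1 fell. Of 25 genes of complexes II to IV 3 rose, namely cytochrome c (Cycs, 0.34), Cyc1 (0.28) and Sdhc (0.19), and 17 did adjusted over the list alone. Among varying genes Sdhc passed without (adjusted p = 0.0236) but not with the replicate block (0.0542). In the tricarboxylic acid cycle 6 of 17 genes rose, including Pcx (0.87), Fh1 (0.37), Dlat (0.28) and Mdh2 (0.22), and 12 did adjusted over the list alone. Of 53 mitochondrial ribosome genes, 22 of which varied, 8 rose and 1 fell, with Mrps22 at 0.39, Mrpl2 at 0.37, Mrpl34 at 0.30 and Mrps17 at 0.20. Adjusted over the list alone, 28 were higher and 1 lower, but 10 of the 28, and 1 of the 8, were near constant. Mrps17 passed among varying genes without (0.0210) but not with the replicate block (0.0550). The median difference of this list was 0.00032 over all members and 0.17 over varying members.

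Fatty acid oxidation had 2 of 18 genes higher, Acads (0.27) and Etfdh (0.15), and 11 adjusted over the list alone. ATP synthase had 1 of 15 higher, Atp5j (0.14), with 9 higher and 1 lower adjusted over the list alone, of which 1 and 1 were near constant. Atp5j and Etfdh passed among varying genes (0.0286 and 0.0338), but not with the replicate block (0.0707 and 0.0677). All 6 lists were called by camera, with adjusted p from 3.03e-10 for complex I to 0.000323 for ATP synthase, and by fry. None was called when camera estimated the correlation (adjusted p = 0.441 with an estimated correlation for each). The mean of all 6 lists' members was 10.24 ± 0.03 in KO and 10.11 ± 0.03 in WT (SD, n = 4), and higher in KO in all 4 number pairs. It joins only lists that had been called higher, so no p is given for this mean. The 18S control probe sets differed by more (0.44, 0.22 and 0.28) than this mean did (0.14). The mean includes near-constant members, and over the 115 of 162 members that varied the difference was 0.195. Single probe sets and a mean over many genes are unlike measures. The list of mitochondrial biogenesis and dynamics was not called (camera adjusted p = 0.975).

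Lipid synthesis and adipocyte genes moved less evenly. Of 22 genes of lipogenesis and triglyceride synthesis, Gpat3 (0.77) and malic enzyme Me1 (0.47) rose and the desaturase Scd1 fell (-0.09), with 6 higher and 2 lower adjusted over the list alone. Scd1 was the brightest probe set in 3 of the arrays, at the top of the measured range. Its call was lost among varying genes only, without (adjusted p = 0.120) and with the replicate block (0.198), and its sign turned when its probe sets were averaged (0.01). Fatty acid synthase Fasn was 1.03 higher but missed the threshold (adjusted p = 0.0521); among varying genes it passed without (0.0117) and with the replicate block (0.0148). Camera did not call the list (0.3), nor did fry (adjusted p = 0.0697). Its mean was higher in every KO array than in any WT array, and hence in all 4 number pairs (exact paired permutation p = 0.125). It was 10.36 ± 0.10 in KO and 10.17 ± 0.05 in WT (SD, n = 4), a difference of 0.19 (exact permutation p = 0.0286). The mean of 17 lipolysis genes was lower in every KO array than in any WT array (-0.06, exact permutation p = 0.0286). Camera did not call that list either, and 0 of its genes passed. Of 18 mature adipocyte genes 3 rose, including resistin Retn (0.26) and adiponectin Adipoq (0.25), with 4 higher and 1 lower adjusted over the list alone, and the list was not called (0.434). Adipoq passed among varying genes without (0.0192) but not with the replicate block (0.0534). Leptin Lep (-0.38) did not pass over all genes (0.244) or among varying genes (0.0949), but did there with the replicate block (0.0331). Pparg (-0.08) did not pass in any of these fits. Among 23 thermogenic genes, of which 9 varied, 0 passed, also adjusted over the list alone. Cox8b (0.54) passed among varying genes without (adjusted p = 0.0449) and with the replicate block (0.0301). Kcnk3 (-0.25) passed there only with the block (0.0377). Ucp1 was near constant at 6.17 and Ppargc1a differed by -0.10. That list was not called (0.548), and its mean (0.01) and its test had opposite signs.

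A few contractile and cytoskeletal genes fell in KO. Of 21 SRF and MRTF target genes Acta2 (-1.26), Tpm4 (-0.59) and the calponin Cnn2 (-0.51) fell, and 4 did adjusted over the list alone. Among 22 YAP and TEAD targets Gadd45b fell (-0.86), with 1 higher, near constant, and 4 lower adjusted over the list alone. Camera called both lists lower (adjusted p = 0.00101 and 0.0413), but neither with an estimated correlation (adjusted p = 0.441 for both), and with the replicate block the YAP and TEAD list was lost (0.0620). The array means of the SRF and MRTF list gave an exact permutation p of 0.0571 and were lower in KO in all 4 number pairs, where the smallest exact paired permutation p is 0.125. The 18S control probe sets moved with genotype beside these genes (0.44, 0.22 and 0.28). Of 27 collagen and matrix genes Thbs2 (-1.16) and Sparc (-0.28) fell, with 1 higher and 5 lower adjusted over the list alone. The list was not called (0.0563), and Col1a1 differed by 0.07 without passing.

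Among markers of vessels and nerves at most 1 gene per list passed, each lower in KO. Of 20 blood endothelium genes Esam fell (-0.33), and 9 did adjusted over the list alone. Of 16 Schwann cell and nerve genes the myelin enzyme Cnp fell (-0.57), and 7 did adjusted over the list alone. Myelin basic protein Mbp differed by -1.56 without passing over all genes (adjusted p = 0.1), but passed among varying genes without (0.0245) and with the replicate block (0.0272). Of 13 pericyte and smooth muscle genes only Acta2 fell, and 1 did adjusted over the list alone. Of 22 angiogenesis factors, of which 13 varied, 0 passed, and 2 were lower adjusted over the list alone, 1 of them near constant. Among varying genes 1 was higher and 1 lower. Vegfb (0.40) passed there without (adjusted p = 0.0282) and with the replicate block (0.0299), as did Tek (-0.22, 0.0256 and 0.0464). Camera adjusted p values were 9.93e-07, 0.000192, 0.0210 and 0.00990 in that order, all lost with an estimated correlation (adjusted p = 0.441 with an estimated correlation for each). None of these 4 lists was called by fry, except Schwann cell and nerve with the replicate block (fry adjusted p = 0.0372). The array means of the genotypes overlapped for blood endothelium and for angiogenesis factors (exact permutation p = 0.0571 and 0.2), although both were lower in KO in all 4 number pairs (exact paired permutation p = 0.125, the smallest 4 pairs can give). Of 8 lymphatic endothelium genes 0 passed, and 2 were lower adjusted over the list alone, 1 of them near constant; the mean difference was -0.01 and camera did not call the list (0.368).

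The macrophage list as a whole did not separate the genotypes. The mean of 26 macrophage genes was 9.43 ± 0.07 in KO and 9.19 ± 0.48 in WT (SD, n = 4), with 0 genes passing, also adjusted over the list alone, and no call (camera adjusted p = 0.141). The difference was -0.19 in numbers 1 and 2 and 0.67 in numbers 3 and 4. Adgre1, which encodes F4/80, differed by 0.52 (adjusted p = 0.333). Cd9 was lower without overlap of the genotypes (-0.57, adjusted p = 0.0884). It was the only member to pass among varying genes, without (0.0229) and with the replicate block (0.0246). Of 18 progenitor and fibroblast genes Clec3b (0.71) and Cd55 (0.28) rose and Ccn5 fell, with 4 higher and 1 lower adjusted over the list alone and no call (0.217). The T cell list was called higher (0.0408) with 0 of 15 genes passing and 1, near constant, adjusted over the list alone, and this was lost with an estimated correlation (adjusted p = 0.567 with an estimated correlation).

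Further lists were called with few passing members. In the cytosolic ribosome list Rpl35 fell (-0.22), and 2 of 27 genes did adjusted over the list alone (camera adjusted p = 1.80e-05). This call was lost with an estimated correlation (adjusted p = 0.441 with an estimated correlation) and by fry (0.0766). In the fasting and glucocorticoid list Lcn2 fell (-0.51), and 2 of 21 did adjusted over the list alone (camera adjusted p = 0.000288), a call lost with an estimated correlation (adjusted p = 0.441) and by fry (0.0766). The cell cycle list was called higher by camera (0.0113) with 0 of 24 genes passing by either adjustment, and lost with an estimated correlation (adjusted p = 0.451) and by fry (0.0697). Among 18 antioxidant genes Srxn1 (0.31), Sod2 (0.27) and Prdx3 (0.21) were among 5 that rose, and Gpx3 fell (-0.70), with 7 higher and 4 lower adjusted over the list alone. Camera did not call this list (0.321), whereas fry did without (0.0225) and with the replicate block (0.0372).

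In total camera called 16 of 44 lists, 8 higher and 8 lower, and 0 with an estimated correlation. Fry called 11, including antioxidant, glycolysis (0.0206) and erythrocyte genes (0.0486), which camera did not call, or 10 with the replicate block. Of the 35 ways to split the 8 arrays 4 against 4, 7 gave at least 16 called lists, so the number of called lists does not stand apart from other splits of these arrays.

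**Figure D3:**
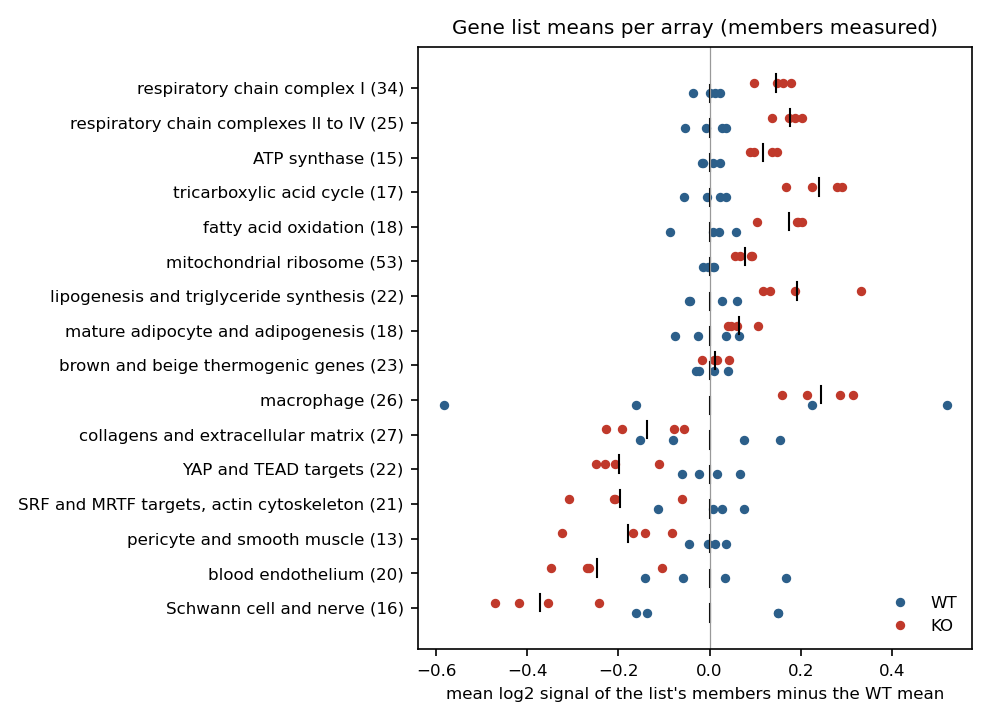
Mean log2 signal of each gene list's measured members minus the WT mean, with a point per array (WT blue, KO red), black lines at the means of 4 arrays and the number of members in brackets. The mitochondrial lists separate the genotypes, whereas the macrophage list spreads widely in WT (SD 0.48).

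Skeletal muscle genes split the arrays by replicate number, not by genotype. Their mean was 8.24 and 8.86 in KO 1 and 2 and 8.57 and 8.40 in WT 1 and 2, but 6.44 and 6.94 in KO 3 and 4 and 6.49 and 6.85 in WT 3 and 4. The KO minus WT difference of the list was 0.04, within the spread of the arrays (exact permutation p = 0.914; camera adjusted p = 0.929, with a sign opposite to the mean). With numbers 1 and 2 against 3 and 4 as a block, a choice made after seeing the data, 493 genes passed, 296 higher and 197 lower. The mean of the mitochondrial lists was 0.14 higher in KO both in numbers 1 and 2 and in numbers 3 and 4.

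**Figure D4:**
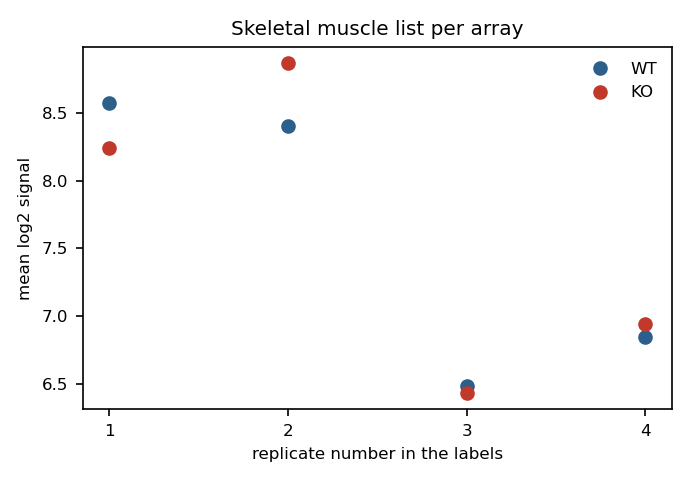
Mean log2 signal of the skeletal muscle list against the replicate number in the labels, with a point per WT (blue) and KO (red) array. Numbers 1 and 2 lie between 8.24 and 8.86 and numbers 3 and 4 between 6.44 and 6.94 in both genotypes.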

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

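The tests of the array labels and of the gene count against other splits were chosen after the result was seen; the splits of the varying-gene count and of the list count were chosen before those counts were seen.

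Of 336 groups of 4 arrays checked, 15 held an array far from the other 3. Chance gives about 1 in 20, so such arrays were no more frequent than by chance. Among mitochondrial genes these were Acadl (11.5 in WT 2, low), Acads (8.74 in WT 2, low), Dlat (9.02 in WT 4, low), Mrpl34 (8.50 in WT 1, low), Ndufb3 (10.9 in KO 1, high) and the mean of the fatty acid oxidation list (10.7 in KO 2, low). Immune genes were Cd3d in KO 4 (7.24, high) and WT 1 (7.08, high), the T cell list mean in WT 1 (6.90, high) and Adgre1 in KO 4 (9.14, high). The others were Adamts5 in KO 2 (10.6, high), Dnajb9 in WT 3 (10.2, high), Pex7 in KO 4 (9.32, low), the glucose transporter Slc2a4 in WT 1 (9.29, low) and the circadian clock list mean in KO 4 (8.0, low).

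The control probe sets for 18S ribosomal RNA, outside the gene test, were higher in all 4 KO arrays than in any WT array. The differences were 0.44, 0.22 and 0.28 for the 3', 5' and middle probe sets (limma adjusted p = 0.0321, 0.0389 and 0.0307 over all probe sets). The log2 ratios of 3' to 5' probe sets were 1.20 in KO and 1.17 in WT for actin (exact permutation p = 0.6) and 0.71 and 0.70 for Gapdh (exact permutation p = 0.8). Whether this difference bears on the gene values was not tested. Among passing probe sets without a single gene name, 63 varied. Those with the largest differences in each direction were 1455918_at (1.07), 1421555_at (0.90), 1423858_a_at (-1.73) and 1431833_a_at (-0.84).

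The Lpar4 probe sets moved in opposite directions. Single swapped or mislabelled arrays were argued against at 1452424_at, chosen because it was lower in KO, where the lowest WT array lay 0.894 above the highest KO array, more than the range within KO (0.172) or WT (0.239). All labels exchanged between the genotypes would leave the same gap; since 2 of the 3 Lpar4 probe sets were higher in every KO array, that exchange cannot be told apart by these values. A transcript that keeps the sequence read by the other 2 probe sets stays open and was not tested.

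The number of changed genes was set against the other splits of the 8 arrays. Only the real split, 1 of 35, reached 733 genes, the highest other giving 36. This argues against chance only if the arrays are unpaired, whereas the numbers met the rule for pairs. A share of 1 in 35 is also the smallest these splits can give, so chance is not excluded. With the numbers taken as pairs only 8 splits part all 4 pairs, too few for a share under 0.05; there the highest other gave 0. With the replicate block itself 0 genes passed in limma, where 3703 had an unadjusted p under 0.05. For varying genes 1 of 35 splits reached 1402, the highest other giving 58, with the same limit. For called lists chance is not excluded, since 7 of 35 splits gave at least 16 and the highest other gave 20, and 2 of the 8 splits that part all pairs gave as many.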

How the results depend on the processing

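The settings that test varying genes only, with or without the replicate block, and the block of numbers 1 and 2 against 3 and 4 were chosen after seeing the data. The 733 passing genes (434 higher, 299 lower) became 0 (0 and 0) with the replicate block in limma, where 3703 genes had an unadjusted p under 0.05, and 9 (7 and 2) with the Welch test. Leaving out an array gave 10 to 253 genes, 4 to 141 higher and 6 to 119 lower, with fewer samples. Varying genes only gave 1402 (769 and 633), sharing 563 of the 590 varying genes, and with the replicate block 1011, of which 478 were lower; leaving out an array there gave 636 to 1149. The block of numbers 1 and 2 against 3 and 4 left 197 lower. Lpar4 at its brightest probe set, 1439665_at (0.53), passed only with varying genes, without and with the replicate block (adjusted p = 0.0300 and 0.0331). Its difference was 0.41 to 0.62 with an array left out. Probe set 1452424_at of the same gene was lower in KO (-1.12). With an estimated correlation 0 lists were called: the adjusted p was 0.441 for 14 of the 16 lists (complex I, complexes II to IV, ATP synthase, tricarboxylic acid cycle, fatty acid oxidation, mitochondrial ribosome, cytosolic ribosome, YAP and TEAD, SRF and MRTF, angiogenesis, blood endothelium, pericyte, Schwann cell, fasting), 0.451 for cell cycle and 0.567 for T cell. With fry 8 lists were lost: blood endothelium, pericyte and cell cycle (0.0697 each), cytosolic ribosome and fasting (0.0766), Schwann cell (0.0769), T cell (0.0902) and angiogenesis (0.112). The replicate block lost YAP and TEAD (0.0620) and changed no other camera call; with fry it ended those of YAP and TEAD (0.174), erythrocyte (0.172) and glycolysis (0.0632) and added Schwann cell (0.0372) and peroxisome (0.0370). The T cell call was lost with array weights (0.0505), median centring (0.164), dim genes left out (0.211), the dimmest left out (0.0735), quantile normalisation (0.154), the block of numbers 1 and 2 against 3 and 4 (0.0734), without shared members (0.0575) and with varying genes without (0.149) and with the replicate block (0.0800). The cell cycle call was lost with median centring (0.130), dim genes left out (0.159), probe sets without shared probes (0.105), quantile normalisation (0.152) and varying genes without (0.397) and with the replicate block (0.447). The pericyte call was lost with dim genes left out (0.0971), quantile normalisation (0.0545), without shared members (0.458) and with varying genes without (0.226) and with the replicate block (0.168). The angiogenesis call was lost with quantile normalisation (0.152), without shared members (0.191) and with varying genes without (0.226) and with the replicate block (0.205). YAP and TEAD was lost without shared members (0.0548), and the cytosolic ribosome with varying genes and the replicate block (0.0800). With an array left out, the number of lists was 12 to 17, and calls were lost for T cell (0.00104 to 0.187), YAP and TEAD (0.0196 to 0.162), angiogenesis (0.00321 to 0.0554), cell cycle (0.00242 to 0.0674) and pericyte (0.0111 to 0.162). Signs turned for Scd1 with the mean of its probe sets (0.0145), Lpl with quantile normalisation (-0.0788) and Polg2 with quantile normalisation (0.00871) and median centring (0.00257). The cause of these changes was not tested, apart from the fewer samples when an array is left out. Signal over background was not analysed here.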

Other observations

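Among the tests weighed here, those of muscle carry-over, of the adipocyte share and of the share of other cells were chosen after the result was seen; the test against abundance-matched lists was chosen before.

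Genes outside the naming rule, chosen after their values were seen, added to those of the report. The imprinted genes Cdkn1c (-0.71) and Plagl1 (-0.38) fell as Peg3 and Zim1 did, while Igf2 (-0.49, adjusted p = 0.0559) and Mest (-0.83, adjusted p = 0.345) did not pass in limma. The secreted Wnt antagonist Sfrp5 fell (-1.08). Enzymes of serine synthesis, Phgdh (0.70) and Psat1 (0.52), rose, and so did the mitochondrial biotin-dependent carboxylase subunits Mccc1 (0.71) and Pcca (0.59) beside Pcx. Genes of peripheral nerve and Schwann cells were lower without passing over all genes, with Mal at -0.99, Kcna1 at -0.84, Cdh19 at -0.70, Dhh at -0.66 and Pmp22 at -0.54. Among varying genes these nerve genes and Igf2 passed with the replicate block (adjusted p from 0.0225 for Pmp22 to 0.0436 for Cdh19) and without it, while Mest did not. These genes were picked by eye and not tested as groups. Mal, Cdh19 and Pmp22 are members of the Schwann cell and nerve list and already count in its test, so they add no separate evidence.

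The mitochondrial lists were higher in KO. Muscle carried over with the fat was argued against, since the lists' mean was still 0.137 higher in numbers 3 and 4, where muscle genes were low in both genotypes. A rise of abundant genes as a class was argued against too, since 10000 random lists matched on mean expression had a mean of -0.00943. The mean of 115 varying members (0.195) stood at percentile 100 of these lists, whose highest was 0.0890. That percentile adds no further support, because the mitochondrial lists had been called higher and the random genes were drawn independently. A higher share of adipocytes cannot be told apart, because the mitochondrial mean minus the mature adipocyte mean was 0.0744 higher in KO with overlapping arrays (exact permutation p = 0.0857); it was higher in all 4 number pairs, by 0.0216 to 0.131, but 4 pairs cannot give an exact paired permutation p below 0.125. After that result was seen, the lipolysis list, already known to be lower in KO, was added to the adipocyte list; the difference was then 0.134 without overlap, which, being picked this way, is not taken to settle the question.

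The mean of the vessel, smooth muscle and Schwann cell lists differed by -0.27; these lists were joined because they had been called lower, so no p is given, and the lymphatic endothelium list, left out of it, differed by -0.01. A lower share of all cells other than adipocytes cannot be told apart from a change in these cells. Their mean minus that of the progenitor and macrophage lists differed by -0.443 with overlapping arrays (exact permutation p = 0.0857), and it was lower in KO in 3 of 4 number pairs. The wide spread of the progenitor and macrophage mean in WT, from 8.63 in WT 3 to 9.37 in WT 1, keeps this open. An effect of the genotype itself on these cells is untested beyond the comparison of the report.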
